A study of Mus musculus with 12 samples.

How the data were processed

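RNA was measured in 12 libraries of prostate luminal cells from wild-type C57BL/6 mice aged 6 to 8 weeks. Per the labels, cells negative for the lineage proteins CD31 (endothelium), CD45 (leukocytes) and Ter119 (red cells) were sorted by surface LY6D, present or absent, and by SCA1, the product of Ly6a, at high, intermediate (int) or low level. This gave 6 populations with 2 libraries each. Per the labels' protocols, RNA was taken up in Trizol and 10 to 20 ng of total RNA went into Lexogen QuantSeq 3' FWD libraries, which read the 3' ends of polyadenylated RNA. A count is therefore a tally of 3' tags, nearly independent of transcript length. No molecular identifiers are named in the labels, so PCR copies of a molecule may be counted more than once.

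Per the submitters' processing notes, the tools were cutadapt 1.9.1, STAR 2.5.1, SAMtools 1.3.1, Picard 1.96, featureCounts, Subread and edgeR, with the mouse build mm10. Their order and settings, the gene annotation and the strand setting of the counting are not given in the sources used here. Raw counts per gene were deposited for 48795 Ensembl gene identifiers, as whole numbers. A table of normalised values was deposited too. These deposited signal values are CPM (counts scaled to a common library size) made with a further factor per library: in each library the deposited count divided by the deposited signal gave 1 factor. These factors differed from edgeR's TMM factors, recomputed over all genes, by a relative 4.4e-16 at most. The raw counts served for all main tests and the deposited normalised values for 1 alternative test.

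Symbols were found for 48349 identifiers in a table of gene names, and the 446 others held 0.475% of all counts. Coordinates are from GENCODE M21 on GRCm38, the assembly that mm10 names, and are counted from 1. Some annotated genes overlap, and some held equal counts, as when a read is counted for more than 1 gene. Of 10635 genes with at least 1000 counts over all libraries, 90 had the same count as another gene in all 12 libraries. Genes that overlap or have near-identical copies (Gsdmc, Gsdmc2 and Gsdmc3; Sbp and Sbpl; Scgb2b15 and Scgb2b17; the H2 genes) are therefore uncertain as to which copy was read, and genes on opposite strands likewise.

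Total counts ran from 8436185 to 20022077 per library. Tests were made in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr by population (15270 genes tested), 1 mean per population over all 12 libraries, glmQLFit and glmQLFTest. The fit has 6 residual degrees of freedom. The common dispersion was 1.65, a biological coefficient of variation of 1.28. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes, and a gene is called below 0.05. Standard errors (SE) of log2 fold changes are the log2 fold change divided by the root of the F statistic. CPM values are scaled by the TMM factors of the tested genes and given as mean ± SD of n = 2 libraries. The series text speaks of biological replicates, but the labels do not say whether these were separate animals or pools, so p-values measure the spread between these libraries.

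The comparisons were LY6D+ against LY6D-, averaged over the SCA1 levels and within each; SCA1high against SCA1low, averaged over LY6D and within each LY6D state; both neighbouring steps of SCA1; and the LY6D by SCA1 interaction. For the LY6D average and the SCA1high against SCA1low average, 23 gene lists were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The neuroendocrine list had 0 tested genes, which left 22. Within a list, calls were also adjusted over the list alone.

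The design, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. Ly6d and Ly6a are given first, as a check of the labels. For both averaged main comparisons the rule takes the 10 highest and 10 lowest log2 fold changes among called genes with a mean log2 CPM of at least 3 and the same direction in both replicate numbers at every level of the other marker. It leaves out genes without a symbol, Gm and Rik names, Ly6d and Ly6a. The other comparisons take 3 per direction, the interaction takes the 6 smallest p-values, and each list gives at most 4 members, by p-value, or by abundance for lists of other cell types. Some genes that the rule takes are not reported here.

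The alternatives were RLE size factors, library size as the only scaling, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, each library left out in turn, a test against a 1.5-fold change (glmTreat), limma-trend on log2 of the deposited CPM plus 1, a model without interaction, and the 4 libraries of a comparison fitted alone. Alternatives added after seeing the data were a subtraction of counts carried over between libraries, leaving out 2 doubted libraries (LY6D- SCA1low replicate 2 and LY6D+ SCA1high replicate 2), leaving out ribosomal RNA features, and a crossed replicate block.

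The procedure was tested on simulated counts with the means and library sizes of the 15270 tested genes. For the LY6D average, 0%, 16%, 36% and 76% of 50 genes changed 2-, 4-, 8- and 16-fold were recovered, with 2 false calls among 66. For SCA1high against SCA1low the shares were 0%, 10%, 22% and 38%, with 1 false call among 36. The changed genes were drawn from those with a mean log2 CPM of at least 3. With no gene changed, the interaction gave 1 call and the other comparisons 0. Of 22 random lists of unchanged genes, camera at the preset correlation called 0 for the LY6D average and 1 for SCA1high against SCA1low. Simulated genes varied independently, so these lists do not test correlated genes. Figures were drawn with matplotlib 3.10.9.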

Results

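The libraries covered 6 sorted populations of mouse prostate luminal cells, the epithelial cells that line the ducts: LY6D+ and LY6D- cells, each at SCA1high, SCA1int and SCA1low, with 2 libraries per population. Totals ran from 8436185 counts in LY6D+ SCA1high replicate 2 to 20022077 in LY6D- SCA1high replicate 2. In each library 7512 to 12202 genes had at least 10 counts. Libraries of 1 population correlated at 0.66 to 0.71 across genes, which are not independent replicates, and 10 of 12 libraries correlated best with a library of another population (0.69 to 0.73). Among these was LY6D- SCA1low replicate 2, at 0.73 with LY6D- SCA1high replicate 1 against 0.68 with its own replicate. Features that overlap the ribosomal RNA repeat on chromosome 17 (CT010467.1, Gm42418 and AY036118, within 39846353 to 39848827) took 6.97% to 24.4% of the counts. Their share was 21.9% ± 3.5 in LY6D+ SCA1low and 21% ± 1.4 in LY6D- SCA1low, against 11.9% ± 7 and 11% ± 2.1 in the SCA1high populations (SD, n = 2).

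The genes of both sorted proteins followed the gates. Ly6d (ENSMUSG00000034634, chromosome 15, 74762056 to 74763620) stood at 303 ± 133, 99.4 ± 49.4 and 45.8 ± 12.5 CPM in LY6D+ cells at SCA1high, SCA1int and SCA1low, and at 2.4 ± 2.06, 1.84 ± 0.559 and 0.7 ± 0.378 CPM in LY6D- cells (SD, n = 2). Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031) stood at 213 ± 45.1, 50.2 ± 7.46 and 8.45 ± 7.19 CPM in LY6D+ cells and at 535 ± 82.3, 125 ± 33.1 and 46.8 ± 31.1 CPM in LY6D- cells. The log2 fold change of Ly6d between LY6D states was 6.25 ± 0.71 (SE, edgeR adjusted p = 1.4e-06), and that of Ly6a between SCA1high and SCA1low was 4.08 ± 0.56 (adjusted p = 3.02e-05). Ly6a was also lower in LY6D+ cells, by a log2 fold change of -1.7 ± 0.42 (adjusted p = 0.0219). This call was lost in 6 of 24 alternatives, among them subtraction of carried-over counts (-1.23 ± 0.84), limma-trend and the fit without both doubted libraries.

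**Figure D1:**
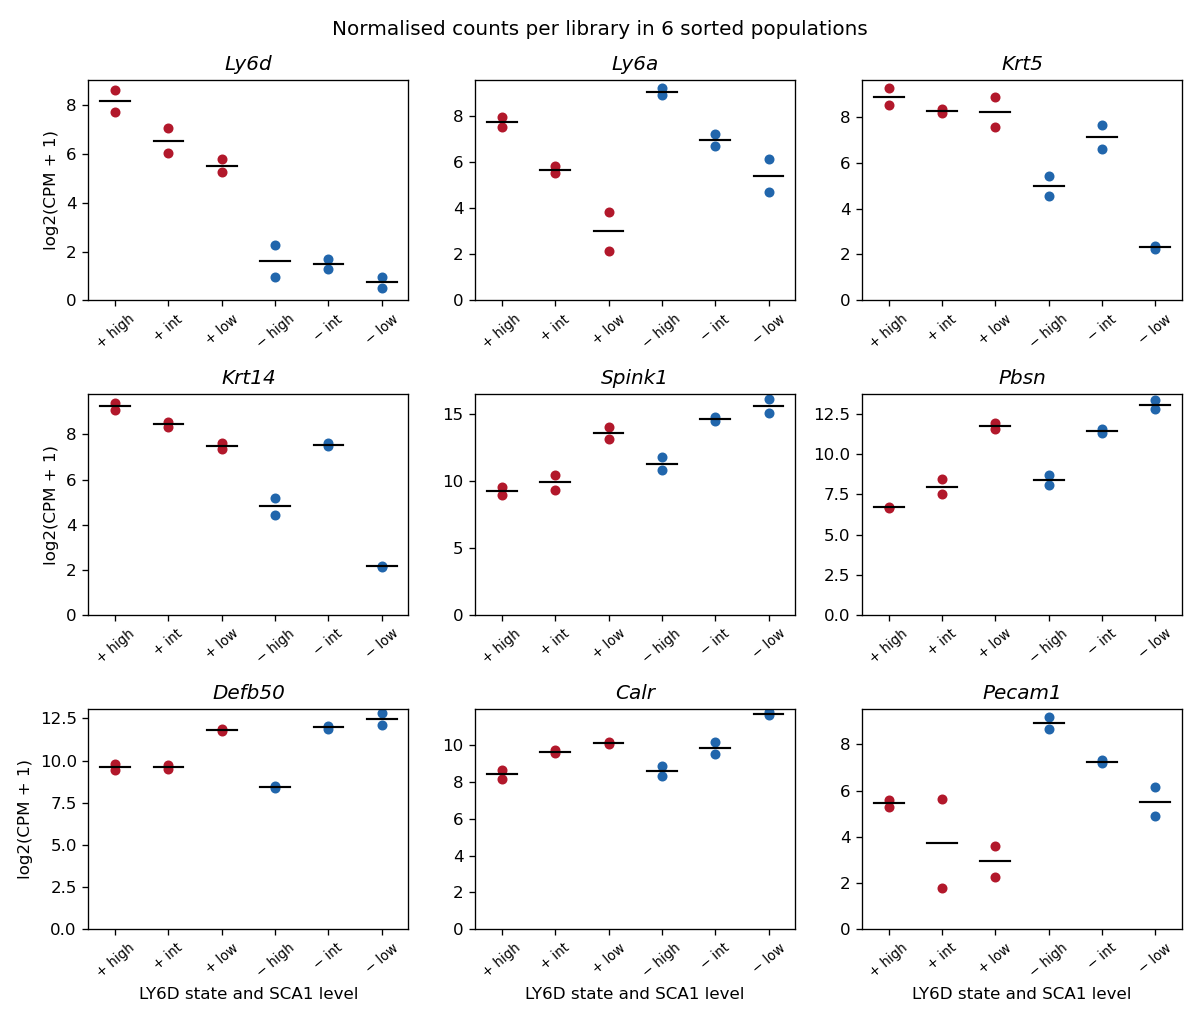
Normalised counts of 9 genes, as log2(CPM + 1), in each of 12 libraries (points; red, LY6D+; blue, LY6D-) by LY6D state and SCA1 level, with the mean of the log2 values of 2 libraries as a line. Krt14 and Krt5 are lowest in LY6D- SCA1low (3.42 and 3.96 CPM), Spink1 and Pbsn are highest there (53100 and 8910 CPM), and Pecam1 is highest in LY6D- SCA1high (487 CPM).

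The first comparison asked how LY6D+ luminal cells differ from LY6D- cells. Basal keratin genes were higher in LY6D+ cells. Whether luminal cells or basal cells in the gate held these transcripts was not tested. Krt5 (chromosome 15, 101707070 to 101712898), which pairs with Krt14 in the filaments of basal epithelial cells, had a log2 fold change of 3.76 ± 0.39 (SE). That of Krt14 (chromosome 11, 100203162 to 100207548) was 3.68 ± 0.35, of Krt15 2.79 ± 0.26 and of Krt17 5.13 ± 0.76. Secretory genes were lower. The log2 fold change of Spink1, a secreted protease inhibitor (chromosome 18, 43728082 to 43737557), was -2.91 ± 0.19. That of Pbsn, which encodes probasin (chromosome X, 77837901 to 77853623), was -2.18 ± 0.16, and of Sbp -2.6 ± 0.27. In CPM, Krt14 stood at 609 ± 99, 349 ± 34.6 and 177 ± 22.2 in LY6D+ cells from SCA1high to SCA1low, and at 28 ± 10.7, 185 ± 10.1 and 3.42 ± 0.183 in LY6D- cells (SD, n = 2). Pbsn stood at 102 ± 3.85, 263 ± 114 and 3460 ± 644 CPM in LY6D+ cells and at 349 ± 103, 2800 ± 361 and 8910 ± 2470 CPM in LY6D- cells. These 7 genes had edgeR adjusted p-values from 2.68e-11 (Spink1) to 0.000102 (Krt17), and each kept its call and direction under all 24 alternatives.

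By list, 10 of 25 basal genes rose and 0 fell (14 rose and 1 fell when adjusted over the list alone), with a camera adjusted p of 1.61e-14 at the preset and 0.0196 at the estimated correlation. The median log2 fold change of the basal list was 2.36, 0.91 and 3.92 within SCA1high, SCA1int and SCA1low, where edgeR called 4, 0 and 5 of its genes (6, 0 and 15 higher and 1, 0 and 0 lower when adjusted over the list alone). Within SCA1int 3 had an unadjusted p below 0.05, and DESeq2 called 1. Among 18 genes of stratified keratins and the cornified envelope, Sfn (2.35 ± 0.24) and Evpl (6.47 ± 1.71; call lost at 6.52 ± 2.2 after subtraction of carried-over counts) rose (6 rose and 1 fell when adjusted over the list alone, adjusted p = 0.0334 with an estimated correlation). Of 28 secretory luminal genes, 8 fell and 0 rose (11 and 0 when adjusted over the list alone, adjusted p = 0.0259 with an estimated correlation). The median of the secretory luminal list was -0.71, -2.49 and -1.25 within SCA1high, SCA1int and SCA1low. There edgeR called 2, 6 and 3 lower and 1, 0 and 0 higher, so a fall of the whole list at SCA1high is not shown. Of 41 genes of the secretory pathway and unfolded protein response, 4 fell: the chaperone gene Hspa5 (-0.65 ± 0.14), Sdf2l1 (-3.64 ± 0.81; call lost at -3.16 ± 0.99 after subtraction), Pdia6 (-1.2 ± 0.29) and Calr (-0.67 ± 0.18) (12 when adjusted over the list alone, adjusted p = 0.0259 with an estimated correlation). The median of this list was -0.23, -1.27 and -0.99 within SCA1high, SCA1int and SCA1low, and edgeR called 0, 1 and 1 of its genes (3, 12 and 9 at an unadjusted p below 0.05; DESeq2 3, 4 and 9), so a fall at SCA1high is not shown. Of 38 interferon and MHC class I genes, 9 fell and 0 rose (17 fell when adjusted over the list alone, adjusted p = 0.0309 with an estimated correlation). Among them were Iigp1 (-3.62 ± 0.4), H2-D1 (-1.49 ± 0.23), B2m (-1.08 ± 0.22) and Irf1 (-1.35 ± 0.31), of which Iigp1 and Irf1 lost their calls after subtraction of carried-over counts, at -3.08 ± 0.83 and -1.26 ± 0.33. Endothelial genes fell along with them: 9 of 18 were called lower (18 when adjusted over the list alone), and the adjusted p was 0.0334 with an estimated correlation. Kdr and Flt1, which encode VEGF receptors, had log2 fold changes of -3.63 ± 0.54 and -3.04 ± 0.52. CD31-positive cells had been gated out, yet Pecam1, which encodes CD31, stood at 487 ± 122 CPM in LY6D- SCA1high, where Iigp1 (847 ± 176 CPM) and Irf1 (1200 ± 64 CPM) were also highest.

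Of 36 immediate early and heat shock genes 8 were higher in LY6D+ cells on average over the SCA1 levels, with Egr1 at 0.88 ± 0.13, Ccn1 at 1.59 ± 0.26, Junb at 0.92 ± 0.16 and Nr4a1 at 1.02 ± 0.19 (11 rose and 2 fell when adjusted over the list alone, adjusted p = 0.0516 with an estimated correlation). The median log2 fold change of this list was 0.16, 0.27 and 1.08 within SCA1high, SCA1int and SCA1low, and its mean log2(CPM + 1) was 6.72 ± 0.18 in LY6D- SCA1low and 7.69 to 7.98 in the 5 other populations, so the average does not show a rise at each SCA1 level. Of 50 ribosomal protein genes, 13 rose and 49 had positive log2 fold changes with a median of 0.56 (34 rose when adjusted over the list alone, adjusted p = 0.474 with an estimated correlation). With RLE size factors and in DESeq2 0 of the 50 were called, so the calls of Rplp2, Rpl23 and Rps19 ended with the others. The aldehyde dehydrogenase genes Aldh1a7 (3.09 ± 0.61), Aldh1a1 (1.64 ± 0.39) and Aldh2 (0.89 ± 0.24) rose among 34 genes of glutathione and xenobiotic metabolism (5 when adjusted over the list alone, adjusted p = 0.139 with an estimated correlation). Aldh2 lost its call in 16 of 24 alternatives and Aldh1a1 in 5, subtraction among them (0.85 ± 0.25 and 1.61 ± 0.51). Of 15 mitochondrial-encoded genes, mt-Co1 fell (-0.63 ± 0.14), and 9 fell when adjusted over the list alone (adjusted p = 0.565 with an estimated correlation). Among 25 proximal luminal genes Cp (3.11 ± 0.42) and Lcn2 (5.68 ± 1.01) rose and Tspan1 (-1.49 ± 0.35; call lost at -1.96 ± 0.71 after subtraction of carried-over counts) fell, and the list did not pass (camera adjusted p = 0.61). Camera did not call the androgen response, cell cycle, cholesterol synthesis, polyamine synthesis or oxidative phosphorylation lists. Nor did it call those of fibroblasts and smooth muscle (adjusted p = 0.0951), leukocytes, erythroid cells, ionocyte-like cells, seminal vesicle or urothelium. The medians of the leukocyte and urothelium lists lay near 0 (-0.04 and 0.04) and differed in sign from camera's direction. Dcn, of the fibroblast list, was higher in LY6D+ cells (1.48 ± 0.22) and Igfbp7, of the same list, lower (-2.77 ± 0.5). After subtraction Igfbp7 lost its call and its fold shrank to -1.9 ± 0.71.

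In all, 379 of 15270 genes were called between LY6D states, 194 higher and 185 lower in LY6D+ cells, and 3116 had an unadjusted p below 0.05. The 10 highest under the rule were Tmem216, Pex7, Clvs1, Dmwd, Efna4, Usp15, Nrtn, Pgf, Med6 and Shh, with log2 fold changes from 8.51 ± 2.05 (Tmem216) to 6.62 ± 1.81 (Shh). Among the 10 lowest were Scgb2b15, Scgb2b17, Zfp764, Prkar2b, Camsap3, Bex4, Hdac9, Phf11d and Gbp3, from -7.52 ± 1.35 to -6.26 ± 1.52 (Gbp3). These folds rest on near-zero counts on 1 side and depend on the prior count of the fit, and Scgb2b15 and Scgb2b17 had equal counts in every library, so the copy read is uncertain. After subtraction of carried-over counts, 191 genes were called (82 higher, 109 lower, 175 of them shared with the 379), and of the rule's genes 1 of the 10 highest and 4 of the 10 lowest kept their call. RLE size factors gave 106 higher and 190 lower genes, and leaving out both doubted libraries gave 397 genes, where 0 of the 10 highest and 7 of the 10 lowest kept their call.

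Within single SCA1 levels the same comparison called 40 genes in SCA1high (21 higher, 19 lower in LY6D+), 31 in SCA1int (3 and 28) and 72 in SCA1low (58 and 14), with 1790, 942 and 1840 genes at an unadjusted p below 0.05. In SCA1high, Slco4a1 (6.73 ± 1.41), Ackr4 (6.67 ± 0.87), an atypical chemokine receptor gene, and Tns4 (6.49 ± 1.44) were higher in LY6D+ cells. Mcam, Adamts9 and the endothelial adhesion gene Sele were lower, at 0.118 ± 0.166, 0.208 ± 0.0392 and 0.46 ± 0.0147 CPM in LY6D+ and 189 ± 5.87, 178 ± 21.1 and 225 ± 75.1 CPM in LY6D- cells (SD, n = 2). In SCA1int, the nuclear RNA Malat1 was higher (0.84 ± 0.17), and Snora30 (-8.19 ± 1.75), Spink1 (-4.6 ± 0.35) and Msmb (-4.14 ± 0.57) were lower, with Msmb at 45.1 ± 7.46 against 797 ± 16.2 CPM. Malat1 lost its call in 4 of 24 alternatives, DESeq2 among them, and Snora30 in 6. In SCA1low, Tpm2 (9.02 ± 2.05), Lcn2 (8.4 ± 1.98) and Tns4 (8.21 ± 1.56) were higher, and Egfl7 (-4.42 ± 1.03), Emp1 (-3.35 ± 0.54) and Iigp1 (-3.26 ± 0.68) lower. Of the genes called in SCA1high and in SCA1low 13 were higher in both (0.0798 by chance), 7 lower in both (0.0174 by chance) and 0 opposite. These comparisons share no library but are linked, since LY6D- SCA1low replicate 2 held 10.7% of the level of genes specific to LY6D- SCA1high replicate 1. Both also share 1 estimate of spread per gene, and the chance values take each gene as equally likely to be called. Those values may therefore be too low. Subtraction of carried-over counts left 7 genes in SCA1high, 6 higher and 1 lower, of which 4 were higher in SCA1low too (0.0148 by chance) and 0 lower in both. With both doubted libraries left out 18 were higher in both (0.176 by chance), 16 lower in both (0.0815 by chance) and 1 opposite. Subtraction kept the call of Ackr4 and ended those of Slco4a1 (9.62 ± 1.76 after it), Tns4 (7.13 ± 1.71), Mcam (-10.89 ± 1.95 before and -10.88 ± 2.82 after), Adamts9 (-9.71 ± 1.91 and -9.77 ± 2.27) and Sele (-8.91 ± 1.67 and -8.96 ± 2.05), where the error grew. Subtraction also ended those of the 6 genes named in SCA1low, with the error larger in each, at 8.71 ± 2.35 (Tpm2), 8.33 ± 2.67 (Lcn2), 8.02 ± 1.79 (Tns4), -4.84 ± 1.18 (Egfl7), -3.34 ± 1.23 (Emp1) and -0.79 ± 1.35 (Iigp1, whose fold shrank most). RLE size factors changed the SCA1low calls to 35 higher and 28 lower.

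The next comparison followed SCA1. Cells at SCA1high had less of the secretory transcripts than SCA1low cells. Pbsn had a log2 fold change of -4.88 ± 0.23 (SE), Spink1 of -4.35 ± 0.25, Defb50, a beta-defensin gene, of -3.14 ± 0.19 and Sbp of -4.31 ± 0.36. Spink1 stood at 2650 ± 1210, 25400 ± 3650 and 53100 ± 25900 CPM in LY6D- cells from SCA1high to SCA1low, and at 625 ± 166, 1050 ± 554 and 13000 ± 5600 CPM in LY6D+ cells (SD, n = 2). Chaperone genes of the endoplasmic reticulum fell with them: Calr by a log2 fold change of -2.39 ± 0.24, Hsp90b1 of -2.25 ± 0.31, Hspa5 of -1.03 ± 0.18 and Sdf2l1 of -6.75 ± 1.15. Wfdc2 (4.03 ± 1.01), which encodes a secreted protease inhibitor, and Clu (2.31 ± 0.54), which encodes clusterin, were higher in SCA1high cells. Adjusted p-values from edgeR ran from 6.05e-15 (Pbsn) to 0.0382 (Wfdc2). Wfdc2 and Clu lost their calls after subtraction of carried-over counts (5.52 ± 1.54 and 2.67 ± 1.02). Hspa5 lost its call in 3 of 24 alternatives, library size as the only scaling among them. Its log2 fold change ranged from -1.31 to -0.53 over these 24.

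By list, 9 of 28 secretory luminal genes fell (14 when adjusted over the list alone) and 11 of 41 genes of the secretory pathway and unfolded protein response fell (19 when adjusted over the list alone), each with a camera adjusted p of 0.0057 at the estimated correlation. Of 15 mitochondrial-encoded genes, 12 fell and all 15 had negative log2 fold changes, with mt-Rnr1 at -1.99 ± 0.19, mt-Co1 at -1.33 ± 0.17 and mt-Nd5 at -2.33 ± 0.31 (15 fell when adjusted over the list alone, adjusted p = 0.0709 with an estimated correlation). Of 7 seminal vesicle genes, Svs5 (-3.91 ± 0.55), Svs4 (-4.68 ± 0.69), Pate4 (-2.61 ± 0.56) and Spinkl (-5.6 ± 1.02) fell (5 when adjusted over the list alone, adjusted p = 0.0713 with an estimated correlation). Pate4 lost its call in 3 of 24 alternatives, and its log2 fold change ranged from -3.27 to -0.79 over these 24. In LY6D+ SCA1low, Svs5 stood at 4680 ± 4840 CPM, a spread as large as the mean. Higher in SCA1high were 3 of 25 proximal luminal genes (7 rose and 2 fell when adjusted over the list alone, adjusted p = 0.0709 with an estimated correlation). So were 4 of 25 basal genes, Krt14 (2.41 ± 0.41), Krt15 (1.46 ± 0.3), Sparc (1.52 ± 0.36) and Krt5 (1.8 ± 0.45) (4 when adjusted over the list alone, adjusted p = 0.145 with an estimated correlation). Krt14, Krt15, Sparc and Krt5 lost their calls in 1, 4, 7 and 11 of 24 alternatives. The median of the basal list was 0.05 within LY6D+ cells, with 13 of 25 genes positive, and 2.64 within LY6D- cells, with 21 of 25, so a rise of the list within LY6D+ cells is not shown. Also higher were 3 of 38 interferon and MHC class I genes, Iigp1 (2.46 ± 0.47), H2-D1 (1.37 ± 0.28) and Irf1 (1.62 ± 0.38) (5 when adjusted over the list alone, adjusted p = 0.0713 with an estimated correlation). Iigp1 lost its call after subtraction of carried-over counts, at 4.5 ± 1.09, and Irf1 lost its call in 7 of 24 alternatives. Of 36 immediate early and heat shock genes 3 rose, Ier3 (1.36 ± 0.21), Fosl2 (1.78 ± 0.35) and Ier5 (1.68 ± 0.42; call lost in 13 of 24 alternatives) (8 rose and 2 fell when adjusted over the list alone, adjusted p = 0.0709 with an estimated correlation). The median of this list was 0.2 within LY6D+ and 0.77 within LY6D- cells. For proximal luminal genes these medians were 0.53 and 2.3, and for interferon and MHC class I genes 1.01 and 2.75. The differences between LY6D states were not tested for any list. Gsdmc rose among 18 genes of stratified keratins and the cornified envelope (1 when adjusted over the list alone, adjusted p = 0.0713 with an estimated correlation).

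Markers of other cell types moved with SCA1 too. Of 20 fibroblast and smooth muscle genes 3 rose, among them Gsn (2.37 ± 0.34) and Igfbp7 (3.68 ± 0.63) (8 when adjusted over the list alone, adjusted p = 0.0494 with an estimated correlation). Of 18 endothelial genes 5 rose, among them Esam (3.25 ± 0.65), Kdr (2.6 ± 0.63) and Flt1 (2.44 ± 0.62) (7 when adjusted over the list alone, adjusted p = 0.144 with an estimated correlation). Kdr lost its call in 8 of 24 alternatives, and Flt1 in 5, among them subtraction of carried-over counts (4.12 ± 1.17). Esam stood at 843 ± 207 CPM in LY6D- SCA1high and at 111 ± 108 CPM in LY6D+ SCA1high. The glutathione and xenobiotic list passed camera with 0 genes called (2 when adjusted over the list alone, adjusted p = 0.0896 with an estimated correlation). Camera did not call the androgen response, cell cycle, cholesterol synthesis, polyamine synthesis, oxidative phosphorylation, ribosomal protein, leukocyte, erythroid, ionocyte-like or urothelium lists. The ribosomal protein list, not called here (adjusted p = 0.249), was lower with RLE size factors (adjusted p = 0.00299) and higher with library size as the only scaling (adjusted p = 0.0407), so no direction can be given. The cell cycle list passed with RLE size factors alone (adjusted p = 0.0436, against 0.0645). The leukocyte list held 1 called gene, Cd52 (-5.88 ± 1.34; call lost at -6.22 ± 1.56 after subtraction; adjusted p of the list 0.566). The median of the urothelium list (0.53) differed in sign from camera's direction.

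**Figure D2:**
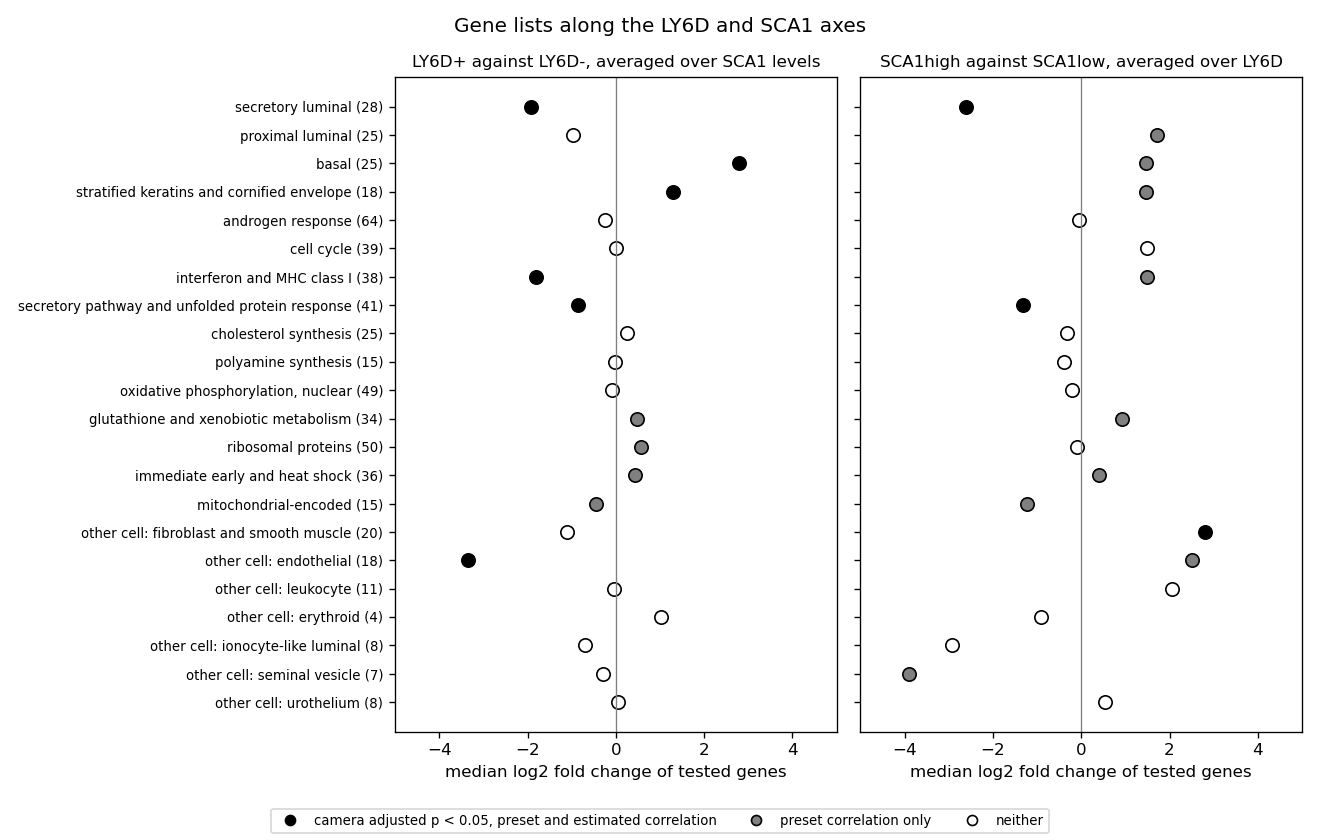
Median log2 fold change of the tested genes of 22 lists (number tested in brackets) for LY6D+ against LY6D- (left) and SCA1high against SCA1low (right). Black points passed camera with both the preset and the estimated correlation, grey points with the preset one alone, and open points with neither. Secretory luminal genes lie at -1.92 and -2.6, basal genes at 2.79 and 1.46, and endothelial genes at -3.34 and 2.52.

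Between SCA1high and SCA1low 185 genes were called, 66 higher and 119 lower in SCA1high, and 1843 had an unadjusted p below 0.05. Under the rule the highest included the gasdermin genes Gsdmc (4.43 ± 0.91), Gsdmc2 (4.4 ± 0.76) and Gsdmc3 (4.24 ± 0.7), near-identical copies whose reads may be shared, then Wfdc2, Eln (3.97 ± 0.98), Helz2 (3.78 ± 0.89), Igfbp7, Fabp4 (3.66 ± 0.63) and Ptprb (3.64 ± 0.84). Among the lowest were the tight junction gene Cldn8 (-8.97 ± 2.31), Gsdma (-8.12 ± 1.17), Plac8 (-8.05 ± 1.6), Mfsd2a (-7.69 ± 1.94), Fkbp11 (-7.58 ± 1.44), the prolactin receptor gene Prlr (-7.55 ± 1.35), Surf6 (-7.17 ± 1.77), Ms4a5 (-6.85 ± 1.75) and Sdf2l1. Calls were lost in 13 of 24 alternatives for Eln, 12 for Wfdc2, 11 for Cldn8 and Surf6, 10 for Mfsd2a and 8 for Ms4a5. The balance of directions followed the scaling: RLE size factors gave 35 higher and 157 lower genes, and library size alone 184 higher and 77 lower, as the median log2 fold change of all genes moved from 0.15 to -0.12 and 0.63. After subtraction of carried-over counts 7 of the 10 highest and 7 of the 10 lowest kept their call, and leaving out both doubted libraries gave 253 genes, where 6 of the 10 highest and 7 of the 10 lowest kept theirs.

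Of the neighbouring steps, SCA1int against SCA1low changed 51 genes (12 higher, 39 lower, 1473 at an unadjusted p below 0.05) and SCA1high against SCA1int 21 (2 higher, 19 lower, 1348 at an unadjusted p below 0.05). In the lower step the carboxypeptidase gene Scpep1 (3.89 ± 0.51), Krt14 (3.37 ± 0.43) and Lgals7 (2.7 ± 0.44) were higher in SCA1int, and the renin gene Ren1 (-4.85 ± 0.91), Svs4 (-3.53 ± 0.66) and Mmp7 (-3.24 ± 0.48) lower. In the upper step Gsn (1.76 ± 0.33) and Emp1 (1.72 ± 0.36) were higher in SCA1high, and Fcgbp (-3.07 ± 0.48), Tcaf3 (-3.02 ± 0.43) and Pbsn (-2.18 ± 0.2) lower, with edgeR adjusted p-values from 1.36e-07 (Pbsn) to 0.0391 (Emp1). Emp1 and Mmp7 lost their calls after subtraction of carried-over counts, at 2.8 ± 0.85 and -3.81 ± 0.91, with larger errors. With both doubted libraries left out the counts were 138 and 53, and library size as the only scaling gave 35 higher and 28 lower genes in the lower step.

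Within each LY6D state, SCA1high differed from SCA1low in 50 genes of LY6D+ cells (6 higher, 44 lower, 1314 at an unadjusted p below 0.05) and in 97 genes of LY6D- cells (37 higher, 60 lower, 1015 at an unadjusted p below 0.05). In LY6D+ cells Gsdmc2 (5.73 ± 1.14), Gsdmc3 (5.47 ± 1.05) and Emp1 (3.29 ± 0.54) were higher, and Prlr, Gsdma and Fkbp11 lower, at 0.0225 ± 0.0318, 0.0674 ± 0.0954 and 0.0225 ± 0.0318 CPM against 132 ± 52.3, 119 ± 95.1 and 42.8 ± 32.7 CPM (SD, n = 2). In LY6D- cells Fabp4 (3.79 ± 0.9), Dusp6 (3.67 ± 0.52), which encodes a MAP kinase phosphatase, and S100a10 (3.57 ± 0.8) were higher, and Tcaf3 (-4.88 ± 0.66), Defb1 (-4.72 ± 0.88) and Pbsn (-4.68 ± 0.32) lower. These comparisons share no library, and 34 genes were lower and 4 higher in both (0.173 and 0.0145 by chance), with 0 opposite. They do share 1 estimate of spread per gene, and the chance values take each gene as equally likely to be called. Those values may therefore be too low. After subtraction of carried-over counts 27 were lower and 2 higher in both, and with both doubted libraries left out 45 and 8. Library size alone gave 13 higher and 34 lower genes in LY6D+ cells and 96 and 40 in LY6D- cells, RLE 20 and 117 in the latter. Subtraction of carried-over counts left 30 and 121 genes, and Emp1, Prlr and Fkbp11 lost their calls in LY6D+ cells. Their log2 fold changes went from 3.29 ± 0.54 to 3.92 ± 1.26 (Emp1), from -11.76 ± 2.26 to -11.8 ± 2.59 (Prlr) and from -10.15 ± 2.29 to -10.19 ± 2.73 (Fkbp11), so the errors grew and the folds did not shrink.

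The LY6D effect differed between SCA1 levels for 11 genes (edgeR interaction test, 1087 at an unadjusted p below 0.05). Defb50 was higher in LY6D+ cells at SCA1high (1.18 ± 0.25) and lower at SCA1int (-2.34 ± 0.25), with an edgeR adjusted p of 9.93e-06 for the interaction. Ackr4 differed strongly at SCA1high and SCA1low (6.67 ± 0.87 and 8.19 ± 0.94) and by 0.56 ± 0.68 at SCA1int, since LY6D- SCA1int cells held 202 ± 64.1 CPM (adjusted p = 0.00233). The metallothionein gene Mt2 was higher in LY6D+ cells at SCA1high (1.97 ± 0.25, adjusted p of the interaction 0.00356), Tgm2 at SCA1low (3.96 ± 0.51, 0.00466) and Dusp6 at SCA1low (5.35 ± 0.57, 0.00701), while Spink1 was lowest relative to LY6D- cells at SCA1int (-4.6 ± 0.35, 0.00466). RLE size factors left 4 genes and subtraction of carried-over counts 12, of which 7 were among the 11. Of the 6 genes named here Spink1 and Dusp6 lost their calls with RLE, and Tgm2 after subtraction. With both doubted libraries left out the count was 49.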

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

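The tests of carry-over and of library scaling on these genes were set before their results were seen, but the subtraction of carry-over is itself an alternative chosen after seeing the data. In 11 genes the LY6D effect differed between the 3 SCA1 levels by the interaction test of edgeR. Their adjusted p-values were 9.93e-06 for Defb50, 0.00233 for Ackr4, 0.00356 for Mt2, 0.00466 for Tgm2 and for Spink1, 0.00701 for Dusp6, 0.00976 for Nfkbia, 0.0161 for Krt14, 0.0279 for Krt5, 0.0326 for Msmb and 0.0445 for Pbsn. Nfkbia, Krt14, Krt5, Msmb and Pbsn are named because the test called them. In 10 of the 11 genes the LY6D log2 fold change was lowest at SCA1int (9 with RLE size factors and 9 after subtraction of carried-over counts). Krt14 stood at 4.44 ± 0.63, 0.91 ± 0.55 and 5.69 ± 0.67 (SE) at SCA1high, SCA1int and SCA1low, Krt5 at 3.91 ± 0.68, 1.03 ± 0.61 and 6.35 ± 0.77, and Msmb at -0.39 ± 0.5, -4.14 ± 0.57 and -0.59 ± 0.5. Other genes were close to the next level. Mt2 stood at -0.19 ± 0.24 at SCA1int against 0 ± 0.24 at SCA1low. Against SCA1high, Tgm2 stood at -0.26 ± 0.45 to 0.36 ± 0.45 and Dusp6 at 1.16 ± 0.48 to 1.77 ± 0.48. A dip at SCA1int common to these genes is therefore not shown. Nfkbia went from -1.55 ± 0.28 to -0.27 ± 0.27 and 0.93 ± 0.28.

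If carry-over of counts between libraries had made these differences, they would shrink once it is subtracted. After it was subtracted 7 of the 11 genes were still called, which argues against carry-over as the source of these 7. Tgm2, Krt14, Krt5 and Pbsn were not. The spread of their LY6D fold changes across levels grew (Krt14 from 4.78 to 5.43, Krt5 from 5.32 to 5.98, Tgm2 from 4.22 to 7.42, Pbsn from 2.05 to 2.7) while the largest SE grew too (from 0.67 to 0.9, 0.77 to 0.93, 0.51 to 1.23 and 0.3 to 0.41). These 4 calls ended as the error grew. Carry-over that hides part of a difference would also give a larger spread after subtraction, so that effect stays open. With library size as the only scaling 10 of the 11 stayed called, all but Pbsn. With RLE size factors Defb50, Ackr4, Mt2 and Tgm2 did, and the calls of Spink1, Dusp6, Nfkbia, Krt14, Krt5, Msmb and Pbsn were lost. The spread of Krt14 was 4.64 and 4.23 under these scalings, and the smallest spread, that of Pbsn, went from 2.05 to 1.89 and 1.41. Scaling thus moved the differences less than their size but decided 7 of the calls under RLE. A difference between the sorted populations stays open, and the design gives no other group in which to test it.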

How the results depend on the processing

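The alternatives set before the counts were seen come first. The subtraction of carried-over counts, the fit without both doubted libraries, the fit without ribosomal RNA features and the crossed block were chosen after seeing the data.

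Between LY6D states 379 genes were called, and between SCA1high and SCA1low 185. DESeq2 called 2208 genes between LY6D states, 1132, 532 and 1663 within SCA1high, SCA1int and SCA1low (40, 31 and 72 in edgeR), and 1303 between SCA1high and SCA1low. It called 764 for SCA1int against SCA1low (51), 516 for SCA1high against SCA1int (21), 1051 and 586 within LY6D+ and LY6D- cells (50 and 97), and 153 for the interaction (11). Limma-trend called 218, then 11 and 7 within SCA1high and SCA1int, 121, 29 and 8 for the 3 SCA1 comparisons, 28 and 62 within LY6D+ and LY6D-, and 1 for the interaction. The cause of these differences between tools was not tested.

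Without a filter on low counts the calls were 94, 52 and 125 within the SCA1 levels, 62 for SCA1high against SCA1int, 94 and 161 within LY6D+ and LY6D-, and 35 for the interaction. A test against a 1.5-fold change called 206 genes between LY6D states, 118 for SCA1high against SCA1low, 30 for SCA1int against SCA1low and 10 for SCA1high against SCA1int, as a stricter hypothesis must lower the count. The model without interaction called 145, 25 and 9 for the LY6D average, SCA1int against SCA1low and SCA1high against SCA1int. The 4 libraries fitted alone gave 84, 12 and 137 within the SCA1 levels and 18 and 262 within LY6D+ and LY6D-, with fewer libraries to estimate the spread. RLE size factors left 4 genes for the interaction. The fold-change test, the model without interaction and the 4-library fit cannot apply to the interaction.

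Subtracting carried-over counts left 191 genes between LY6D states, 7 within SCA1high and 30 for SCA1 within LY6D+. Leaving out both doubted libraries gave 87, 73 and 118 within the SCA1 levels, 138 and 53 for the neighbouring SCA1 steps, 192 within LY6D- and 49 for the interaction. The cause of these rises was not tested.

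Leaving out each of the 12 libraries in turn, where a lone library is assumed to vary like the other groups, gave 286 (without LY6D- SCA1int replicate 2) to 492 genes (without LY6D+ SCA1high replicate 1) between LY6D states. For SCA1high against SCA1low it gave 185 to 304, the highest without LY6D+ SCA1int replicate 1, and 296 without its replicate 2. Within SCA1high, SCA1int and SCA1low it gave 50 to 128, 31 to 62 and 83 to 162, the highest without LY6D- SCA1low replicate 2, LY6D+ SCA1low replicate 2 and LY6D+ SCA1int replicate 2. For SCA1int against SCA1low it gave 47 to 125 (the highest without LY6D- SCA1low replicate 2), with 92, 86 and 77 without LY6D+ SCA1high replicate 2, LY6D+ SCA1int replicate 1 and LY6D+ SCA1low replicate 2. For SCA1high against SCA1int it gave 33 to 70, within LY6D+ 64 to 106, within LY6D- 87 to 206 and for the interaction 18 to 45. The highest of these came without LY6D+ SCA1int replicate 2, except within LY6D+ cells (LY6D- SCA1low replicate 2).

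Of the gene lists, 10 were called between LY6D states and 12 between SCA1high and SCA1low. An estimated correlation left 6 and 3. Leaving out 1 library gave 9 to 10 and 11 to 15.

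The labels do not say what the replicate numbers share, though the library names carry 1 prefix per number. The numbers were not taken to pair the libraries: of 15 pairs of populations 2 had a correlation above 0.1 (range -0.2 to 0.13). Of 12 libraries 6 correlated best with a library of their own number, 5 of them among the 6 LY6D+ libraries, so a shared source is not excluded. With the replicate number as a block 65 genes were called within SCA1high (40 without), and the other counts moved by less than 1.5 times. A crossed block in LY6D- SCA1low gave 402 genes between LY6D states and 223 between SCA1high and SCA1low.

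Of 166 named pairs of gene and comparison none changed direction under an alternative. The model without interaction, the test against a fold change and the 4-library fit covered only part of these pairs. In them the call or its absence was unchanged for 80, 112 and 17 pairs, to be set beside their losses below. Calls were lost for 77 in limma-trend, 55 after subtraction, 52 in the model without interaction, 48 in the test against a fold change, 30 without both doubted libraries, 28 with RLE, 14 with library size, 12 in DESeq2, 11 in the 4-library fit, 5 without the filter, 2 without ribosomal RNA features, and 1 each in both block fits. Leaving out 1 library lost 4 (LY6D+ SCA1int replicate 2) to 38 (LY6D- SCA1low replicate 1), and 30 without LY6D- SCA1high replicate 1. In 54 of the 55 pairs that lost their call after subtraction a log2 fold change was tested. The SE grew in 53 of these and the fold did not shrink in 37, whose lost calls do not show that carry-over made the differences. Iigp1 within SCA1low shrank most, from -3.26 ± 0.68 to -0.79 ± 1.35. Calls were lost in 8 or more of 24 alternatives by 9 of the 10 highest genes between LY6D states under the rule, and among others by Aldh2 (16), Evpl (14) and Calr (8) between LY6D states and by Ier5 (13), Wfdc2 (12), Krt5 (11), Clu (10) and Kdr (8) between SCA1high and SCA1low. Depth and spread limit what can be seen: in simulated data 0% of 2-fold and 16% of 4-fold changes between LY6D states were recovered, so a gene not called is not shown to be unchanged.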

Other observations

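The tests of transfer between libraries, of impure sorting, of endothelial cells in the gate and of other splits of the libraries were chosen only after the results were seen, and the test of carry-over on the endothelial genes before. Mean log2(CPM + 1) over 25 basal genes was 5.69 ± 0.46, 5.79 ± 0.06 and 5.49 ± 0.07 (SD, n = 2) in LY6D+ cells from SCA1high to SCA1low. In LY6D- cells it was 3.96 ± 0.66, 4.93 ± 0.52 and 2.58 ± 0.49. Over 7 seminal vesicle genes it was 4.28 ± 0.13, 4.41 ± 0.82 and 7.79 ± 1.57 in LY6D+ cells and 4.24 ± 0.57, 6.42 ± 0.61 and 6.17 ± 1.46 in LY6D- cells. Genes lower in LY6D+ cells and lower in SCA1high cells numbered 42, where independent lists would share 1.44, and 24 genes were lower in LY6D+ and higher in SCA1high cells (0.8). Those higher in both numbered 9 (0.839), and 2 were higher in LY6D+ and lower in SCA1high cells (1.51). The LY6D list rests on all 12 libraries, the SCA1 list compares 8 of them, and both share 1 estimate of spread per gene. Part of the excess may come from this sharing, and no split of the libraries was made to test it. Genes high in 1 population can also enter both lists. The 24 genes include Esam, Kdr, Flt1, Iigp1, Irf1 and H2-D1, of the endothelial and interferon lists. Mean log2(CPM + 1) of these lists was highest in LY6D- SCA1high, at 7.22 and 6.07, and next in LY6D- SCA1int, at 5.04 and 4.66. The 24 therefore do not show a link between the markers beyond that population. Over 9267 genes the LY6D and SCA1 log2 fold changes correlated at 0.152 (covariance 0.517), against -0.011 (-0.017) in simulated counts with no gene changed. The simulation drew genes independently, with 1 mean for all populations and no carry-over, so a value near 0 was to be expected. It cannot show how much of 0.152 comes from carry-over or from 1 population. Subtraction of carried-over counts changed the lists to 191 and 153 genes, of which 33 were lower in both and 17 lower in LY6D+ and higher in SCA1high. With both doubted libraries left out these were 66 and 30.

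Genes near 0 in most libraries were counted in some other libraries at steady shares. Of 46 genes found at 30 CPM or more in LY6D- SCA1high replicate 1 and at 1 CPM or less in at least 9 other libraries, LY6D- SCA1low replicate 2 held a median of 10.7% of the donor's level (quartiles 9.1% and 11.9%). Of these genes 89.1% lay within 2-fold of the median ratio, as a transfer of reads or molecules between libraries needs. SCA1high cells sorted into the SCA1low tube of the same replicate would bring genes of LY6D- SCA1high replicate 2, and the share taken from that library was 0.18%, which argues against that source unless the replicate numbers of tubes were crossed. Of 132 pairs of libraries 12 had a share of at least 1%, with a median of 0.147% over all pairs. Apart from the 10.7% pair and a pair at 5.09%, both with LY6D- SCA1low, these 12 lay within 1 replicate number as labelled. The larger shares thus mostly followed the replicate number. Not all 12 were as steady: from LY6D- SCA1int replicate 2 to LY6D+ SCA1int replicate 2, 65.4% of genes lay within 2-fold of the median ratio. The next highest shares were 7% from LY6D+ SCA1high replicate 2 to LY6D+ SCA1int replicate 2 and 5.09% from LY6D- SCA1low replicate 1 to LY6D- SCA1high replicate 2. With the numbers of LY6D- SCA1low crossed, the 10.7% and 5.09% pairs would each lie within 1 replicate number. Of the 12 pairs, only that from LY6D- SCA1high replicate 1 to LY6D- SCA1low replicate 1, at 1.67%, would then not. Crossed numbers thus stay open, and with them impure sorting within a replicate. Whether a transfer happened at the bench, on the sequencer or through a mixed tube stays open.

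Endothelial genes were highest in LY6D- SCA1high, with a mean log2(CPM + 1) of 7.22 ± 0.37 over 18 genes, against 3 ± 0.4 in LY6D+ SCA1high, 5.04 ± 0.29 in LY6D- SCA1int and 4.28 ± 0.62 in LY6D- SCA1low. Esam, Flt1, Egfl7 and Kdr stood there at 843 ± 207, 837 ± 124, 541 ± 54.5 and 427 ± 50 CPM. All 18 were higher in LY6D- than in LY6D+ SCA1high cells, although 0 passed the edgeR test singly within SCA1high (12 when adjusted over the list alone, 13 at an unadjusted p below 0.05, 12 called by DESeq2). Their median log2 fold change went from -3.76 to -3.8 after subtraction, which could not shrink it, since no other library held more of these genes. By library the mean was 6.96 and 7.48 in LY6D- SCA1high and 5.24 at most elsewhere (LY6D- SCA1int replicate 2). Small shares of lower libraries cannot raise a library above them, which argues against carry-over as the source. Endothelial cells in the gate are a candidate source. The CD31 gate should have removed them, and none of the 18 genes is in another list used here, but whether the sorted luminal cells express these genes themselves was not tested. Ptprc, which encodes CD45, did not exceed 0.216 CPM in any library. Over 4 erythroid genes the mean log2(CPM + 1) ran from 0.94 in LY6D+ SCA1high replicate 1 to 7.63 in LY6D- SCA1low replicate 1. Replicates differed, with 6.66 in LY6D+ SCA1high replicate 2 and 1.42 in LY6D- SCA1low replicate 2. Red cell RNA in some libraries is thus not excluded.

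Counts of called genes were compared with other splits of the libraries, in the model without interaction. For LY6D, 1 of 60 splits (of 462 possible), the real one, gave 145 genes or more, and the highest other gave 5. For SCA1high against SCA1low 1 of 35 did (127 against 5), for SCA1int against SCA1low 1 of 35 (25 against 23) and for SCA1high against SCA1int 1 of 35 (9 against 3). The other splits mix the sorted populations, so real differences between populations can widen their spread and lower their counts. For the SCA1 comparisons 1 of 35 is also the smallest share that could occur. The splits therefore cannot exclude chance for these 4 counts, and for SCA1int against SCA1low another split came close.

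Xist, transcribed from the inactive X chromosome, was counted at 16.6 and 24.5 CPM in both LY6D+ SCA1int libraries and at 1.23 CPM or less in the 10 others. Ddx3y, on the Y chromosome, was counted in all 12 libraries, at 8.07 to 352 CPM.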
